A study of Rattus norvegicus with 9 samples.

How the data were processed

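Small RNA libraries were made from brain tissue around the right globus pallidus of male Sprague-Dawley rats at day 21 after surgery. Per the labels' protocols, 3 libraries came from sham-operated rats injected with saline, 3 from rats given 0.5 U of collagenase type VII to cause an intracerebral haemorrhage (ICH), and 3 from rats with the same haemorrhage that received Buyang Huanwu Decoction (BYHWD) by gavage. Per the same protocols, total RNA was pretreated to remove tRNA modifications that block adapter ligation or reverse transcription, inserts of 15 to 50 nt were selected on a gel, and libraries were run for 50 cycles on a NextSeq instrument. Per the submitters' processing notes, the tools were FastQC, cutadapt and Novoalign 2.07.11, and the genome build listed was hg19, a human assembly. Which step used that build for rat reads, the fragment annotation and the counting rule are not given in the sources used here.

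Each library has 1 table with a fragment identifier, a tag count and a TPM value, per the file headers. The tag counts are whole numbers as the authors deposited them, with no normalization. The TPM values, per the file headers, equal the deposited count divided by 1 library total per file and multiplied by 1 constant, which was checked on every listed fragment. The division gave a library total for each file. Because rows repeat, the TPM column was treated as another unit than strict TPM and was used for these totals and for printing levels. The 9 tables held 2122 rows each for 530 fragments. A fragment stood on 1 to 37 rows with identical values, 347 of them on 2 or more rows, and 1 row per fragment was kept. What the repeated rows stand for is not given in the sources used here.

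Library totals ran from 530827 to 1066616 tags, of which the listed fragments held 71.2 to 80.6%. The lowest count above 0 in a library was 76 to 149, or 134 to 152 TPM, so the tables appear to list a fragment in a library only above a minimum. A 0 was therefore read as below that minimum, which does not show an absence of tags, and no limit on a share was computed from a count of 0. For a fragment at 0 in all 3 libraries of a group, the other group's mean TPM is given as a ratio to the mean of the lowest TPM listed in those libraries, a lower limit of the fold only if unlisted fragments lie below that minimum. In all, 311 fragments were above 0 in all 9 libraries and 219 were at 0 in 1 or more. The files pair no identifier with a sequence, a fragment type, a parent tRNA or a gene, and no table used here supplied the match. Planned shares per fragment type, origin and isotype, the tests of fragment lists, and the summing of identical sequences or of fragments of 1 parent tRNA were therefore not run. The planned settings for normalized values were not needed, since the files hold counts.

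Groups were taken from the labels. The numbers 1 to 3 used here only name the libraries of a group in accession order. The labels share no number across groups, so libraries were not paired, and they name no batch. They do not say outright that each library is a separate rat, so p-values measure the spread between these libraries. Libraries were compared in pairs for duplication, and the most similar pair still differed by a chi-square of 34.9 per degree of freedom.

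The main test was edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with TMM factors on the sums of listed counts, filterByExpr by group (minimum count 10), a robust quasi-likelihood fit of all 9 libraries and a quasi-likelihood F-test per contrast. The filter left 455 fragments. Benjamini-Hochberg adjustment covered the fragments tested in a comparison, and the threshold was 0.05. The standard error of a log2 fold change was computed from the fold change and its F statistic, and intervals of fold changes are at 95%. Both therefore restate the unadjusted p of the edgeR test and are not adjusted for the number of fragments tested. Single values such as library shares were compared by a two-sided exact permutation test over the 20 assignments of 3 against 3, whose smallest p is 0.1, with adjustment over 18 tests. The comparisons were ICH against sham, ICH + BYHWD against ICH, ICH + BYHWD against sham, and any difference among the 3 groups. Fold changes of the first pair of comparisons were set against 100 simulated data sets of unchanged groups that share the ICH libraries.

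The edgeR tests, the simulated comparison, the groups, the naming rule and most alternatives were fixed before the data were examined. Permutation tests had been planned only for shares per fragment type, origin and isotype. The 18 that were run were not planned, and the abundant fragments among their measures were picked from these libraries. The rule for named fragments took those past the threshold. With fewer than 10 past it, the 5 higher and 5 lower with the smallest p were added, then the 10 most abundant. The rule also took fragments with opposite directions at an unadjusted p under 0.05, and members of the fragment lists that were not tested. Because the identifiers carry no identity, the text names 2 per direction and comparison and the 2 most abundant. Alternatives were other scaling factors (RLE, upper quartile, none), other filters, DESeq2 1.42.0, limma-voom and limma with trend on log2(CPM + 1) (limma 3.58.1), a fit of the 6 libraries compared, other thresholds, and leaving out each library. Alternatives added after seeing the data were fits on the 311 fragments without a 0, zeros set to a library's lowest listed count, the recovered library totals, and counts summed over fragments that adjoin at 2 or more places of the row order.

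The edgeR procedure was tested on simulated counts, with 200 fragments changed in ICH in each of 20 data sets and ICH compared with sham. Fragment means came from all 9 libraries, and the spread from a fit with zeros at a library's lowest listed count. Each fragment was drawn independently, and values under that count became 0. The results therefore do not cover fragments that vary together. Among fragments without a 0, edgeR called 6.01% of those changed 1.5-fold (815 tests) and 20.4% of those changed 2-fold (746 tests). It called 87.7% of those changed 4-fold (570 tests). Among fragments with a 0 in some library it called 24.2% of those changed 4-fold (715 tests). Unchanged fragments in the same data sets were called in 24 of 4379 tests without a 0 and in 13 of 2182 with a 0. In 20 other data sets without any changed fragment it made 0 calls for ICH against sham, and 1 of the 20 had a call in each of the other 2 comparisons. Counts are of amplified tags without molecular identifiers.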

Results

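The series measured tRNA-derived small RNAs, the fragments cut from mature or precursor tRNAs (tRFs) and the longer stress-induced tRNA fragments (tiRNAs), in rat brain after a collagenase haemorrhage. Collagenase weakens vessel walls so that blood enters the tissue at the injection site, and the sham rats had saline injected at the same place. BYHWD, a herbal decoction of traditional Chinese medicine, was given at 4.36 g/kg once a day for 21 days. Each group had 3 libraries. The library totals were 735460, 715067 and 530827 tags for sham 1, 2 and 3. They were 1066616, 980150 and 888167 tags for ICH 1, 2 and 3, and 799227, 683782 and 1002327 tags for ICH + BYHWD 1, 2 and 3. The total was 660451 ± 112720 in sham and 978311 ± 89239 in ICH (SD, n = 3), and every ICH library was larger than every sham library (exact permutation p = 0.1, the smallest possible, adjusted p = 0.6 over 18 tests). Fragments are given by the identifiers in the files, which do not pair them with a sequence, a parent tRNA or a gene.

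The most abundant fragment, AS-tDR-000052, held 4.47% ± 3.99 of the tags in sham, 10.7% ± 4.39 in ICH and 8.08% ± 2.20 in ICH + BYHWD (SD, n = 3). Its share was 2.27% and 2.1% in sham 1 and 2 but 9.08% in sham 3. In ICH it was 12.0%, 14.2% and 5.76%, so the groups overlapped, and the difference between ICH and sham was within the spread of the libraries (exact permutation p = 0.2). For ICH + BYHWD the exact permutation p was 0.5 against ICH and 0.3 against sham. AS-tDR-001297, the next most abundant, held 7.44% ± 0.69 in sham, 6.37% ± 1.08 in ICH and 7.0% ± 1.52 in ICH + BYHWD (SD, n = 3). The 10 most abundant fragments together held 33.3% of the tags on average. None of the 10 passed the edgeR test in any comparison, and their lowest adjusted p was 0.507.

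The first comparison asked which fragments differ in the tissue around the haemorrhage from the sham-operated tissue. AS-tDR-007988 was at 1403 ± 457 TPM in ICH and 518 ± 103 TPM in sham (SD, n = 3), a log2 fold change of 1.69 (SE 0.48), or 3.22-fold with a 95% interval of 1.49 to 6.99. AS-tDR-007825 was at 347 ± 86.4 TPM in ICH and listed at 0 in all 3 sham libraries. Its ICH mean was 2.34 times the mean of the lowest TPM listed in those libraries. Lower values in ICH were seen for AS-tDR-007227, at 331 ± 84.1 against 744 ± 175 TPM with a log2 fold change of -1.04 (SE 0.20), and for AS-tDR-000393, at 325 ± 57.1 against 606 ± 110 TPM with a log2 fold change of -0.75 (SE 0.16). The adjusted p values were 0.507 for AS-tDR-007988, 0.316 for AS-tDR-007227 and 0.332 for AS-tDR-000393, so none of these differences passed the threshold.

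Of 455 fragments tested with edgeR, 0 were higher and 0 lower in ICH than in sham at an adjusted p under 0.05, and the smallest adjusted p was 0.316. At an unadjusted p under 0.05 there were 24 higher and 17 lower fragments, with 22.75 expected in all by chance. RLE scaling gave 31 and 12, and no scaling gave 19 and 16. These counts rested on single libraries: they were 66 and 18 without sham 3, 48 and 25 without ICH 3, 9 and 6 without sham 1, 4 and 6 without sham 2, 14 and 9 without ICH 1, and 5 and 8 without ICH 2. In 31 fragments every ICH library lay above every sham library and in 54 every one lay below, together 18.7%. Chance gives 10% for a fragment without tied values and at most that where zeros tie. How far this share varies by chance when fragments vary together was not tested. Among the 311 fragments above 0 in all libraries, 44 had a fitted fold above 2 in ICH and 2 had one as large in the other direction, also with 0 past the threshold. DESeq2 called 20 fragments higher and 8 lower, 6 and 8 with zeros set to the lowest listed count, and 5 and 4 on the 311 fragments, and 15 of its 28 calls had a 0 in some library. Limma-voom and limma with trend called 0. Without sham 3, edgeR called 40 higher and 4 lower, and 29 of these 44 were above 0 in every library. When only the 311 fragments were tested it called 1 and 1. Between these 2 fits without sham 3 the log2 fold change of AS-tDR-000393 went from -0.99 to -0.81, and its adjusted p from 0.036 to 0.060. That of AS-tDR-007227 went from -1.31 to -1.15, and its adjusted p of 0.0138 and 0.0457 passed in both. AS-tDR-007988 passed in neither, at 0.066 and 0.101.

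**Figure D1:**
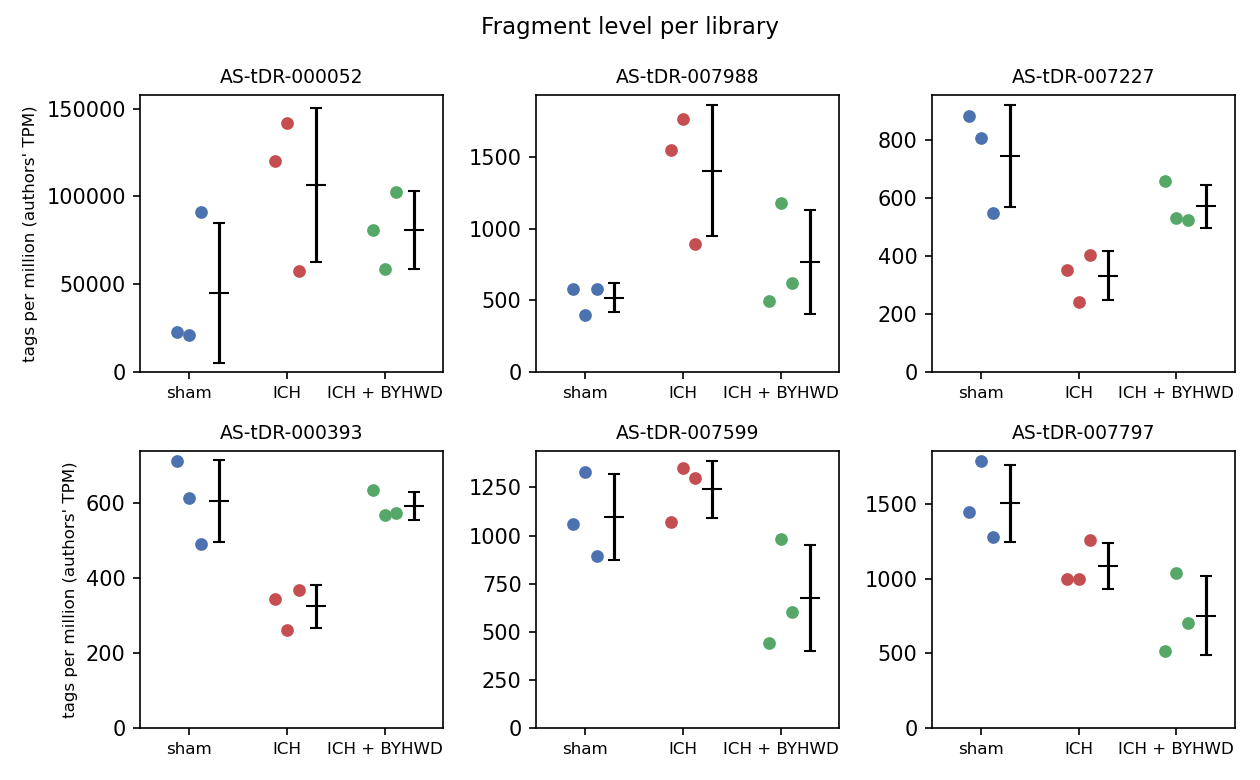
Level of 6 named fragments in each library, as TPM of the authors' library total, with 3 libraries per group as points and the mean ± SD beside them; every axis starts at 0. AS-tDR-000393 lay at 325 ± 57.1 in ICH, below all libraries of the other 2 groups, and AS-tDR-000052 in sham 3 lay above its level in ICH 3.

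The next comparison asked how the decoction altered the fragments in rats with a haemorrhage. AS-tDR-009151 was at 189 ± 9.09 TPM in ICH + BYHWD (SD, n = 3) and listed at 0 in all 3 ICH libraries, which is 1.36 times the mean of the lowest TPM listed there. AS-tDR-000393 was at 593 ± 37 TPM in ICH + BYHWD against 325 ± 57.1 in ICH, a log2 fold change of 0.57 (SE 0.16). AS-tDR-007599 was at 675 ± 277 against 1240 ± 149 TPM, a log2 fold change of -1.23 (SE 0.35), and AS-tDR-010070 at 877 ± 133 against 1276 ± 214 TPM, a log2 fold change of -0.93 (SE 0.29). Each of these 4 fragments had an adjusted p of 0.533 and did not pass the threshold. The size of the fold changes depended on the scaling: without TMM they were 0.92 for AS-tDR-000393, -0.83 for AS-tDR-007599 and -0.48 for AS-tDR-010070. The last was -0.54 with recovered library totals and no TMM, and -0.60 without ICH 2. It was also -0.65 without the low-count filter, and -0.65 without sham 1, sham 2 or sham 3, which are not in this comparison. The value without ICH 2 therefore does not show that ICH 2 carried the difference.

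With edgeR, 0 of the 455 fragments were higher and 0 lower in ICH + BYHWD than in ICH, and the smallest adjusted p was 0.533. At an unadjusted p under 0.05 there were 20 higher and 10 lower, 38 and 4 with upper-quartile factors, and 22 and 2 without scaling. On the 311 fragments above 0 in all libraries the split turned to 12 higher and 20 lower, so the direction of the balance was not settled. Leaving out 1 library gave 6 to 33 higher and 2 to 34 lower, with 33 and 34 without ICH 3, 8 and 2 without ICH 1, and 6 and 6 without ICH 2. Among the 311 fragments, with all 9 libraries, 0 had a fitted fold above 2 in ICH + BYHWD and 30 had one as large in the other direction. Groups did not overlap for 49 fragments higher and 17 lower, or 14.5% where chance gives at most 10%, and the spread of this share by chance was not tested. DESeq2 called 4 higher and 5 lower, of which 8 had a 0 in some library, but 0 and 0 both with zeros set to the lowest listed count and on the 311 fragments. The 1 call without a 0, AS-tDR-007599, had a DESeq2 log2 fold change of -1.25 (adjusted p 0.016). It was -1.06 (0.170) with zeros at that count and -1.25 (0.086) on the 311 fragments. Limma-voom and limma with trend called 0.

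The last comparison asked whether rats treated with the decoction still differed from sham. AS-tDR-007797 was at 753 ± 265 TPM in ICH + BYHWD and 1504 ± 260 in sham (SD, n = 3), a log2 fold change of -1.15 (SE 0.27). AS-tDR-008072 was at 1070 ± 79.0 against 1633 ± 386 TPM, a log2 fold change of -0.76 (SE 0.18). Both had an adjusted p of 0.713. On the higher side, AS-tDR-007043 was at 634 ± 164 against 421 ± 38.2 TPM, a log2 fold change of 0.42 (SE 0.19) with an adjusted p of 0.997. AS-tDR-007825 was listed at 0 in all 3 sham libraries and in 1 of the ICH + BYHWD libraries, so no fold is given.

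With edgeR, 0 of 455 fragments were higher and 0 lower in ICH + BYHWD than in sham. The unadjusted p was under 0.05 for 1 higher and 18 lower fragments, where 22.75 are expected in all by chance, with a split of 3 and 15 under RLE scaling and 2 and 6 without scaling. It was under 0.05 for 4 and 27 with limma-voom and for 12 and 22 with limma with trend. Leaving out 1 library gave 1 to 52 higher and 2 to 23 lower, and the balance turned without sham 3, at 52 and 11, and without sham 1, at 3 and 2. Groups did not overlap for 6 fragments higher and 32 lower, or 8.35% where chance gives at most 10%, and the spread of this share by chance was not tested. DESeq2 called 11 higher and 6 lower, of which 15 had a 0 in some library, but 0 and 1 with zeros set to the lowest listed count and 0 and 3 on the 311 fragments. The 2 calls without a 0, AS-tDR-007797 and AS-tDR-008072, had a DESeq2 adjusted p of 0.056 and 0.225 with zeros at that count. Both were called on the 311 fragments. Limma-voom and limma with trend called 0. Without sham 3, edgeR called 17 higher, of which 15 had a 0 in some library, and 0 when only the 311 fragments were tested. In the test of any difference among the 3 groups, edgeR called 0 fragments, 29 had an unadjusted p under 0.05, and the smallest adjusted p was 0.608. Without sham 3 that test called 27, and the count at an unadjusted p under 0.05 ran from 7 without sham 2 or without ICH 1 to 72 without sham 3.

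The study also asked which changes after haemorrhage the decoction alters. At an unadjusted p under 0.05 in both comparisons, 8 fragments went in opposite directions in ICH against sham and in ICH + BYHWD against ICH, among them AS-tDR-007988, AS-tDR-007227 and AS-tDR-000393. Of the 8, 2 were higher and 6 lower in ICH than in sham, where independent lists would share 0.527 and 0.747. Simulated unchanged groups that share the ICH libraries, with fragments varying independently, gave a median of 5 such fragments and 8 or more in 14 of 100 data sets. Across the 311 fragments the log2 fold changes of both comparisons had a Pearson r of -0.77 and a Spearman rho of -0.73, against a simulated median r of -0.51 and rho of -0.48. The simulated values rest on a median of 340 fragments (327 to 354) above 0 in all libraries of a simulated data set, not on the same 311. Fragments are not independent replicates. The covariance was -0.250 against a simulated median of -0.080. When whole libraries of residuals were reassigned to the 3 groups, which keeps the correlation between fragments, 130 of 1680 reassignments (7.74%) gave a covariance of log2 CPM differences as low as the observed -0.218. The ICH libraries number 3 and could not be split into parts of at least 2, so the excess over the independent simulation, in part or in full, may come from the shared libraries. Without ICH 3 the count was 38, and without ICH 1 it was 3.

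**Figure D2:**
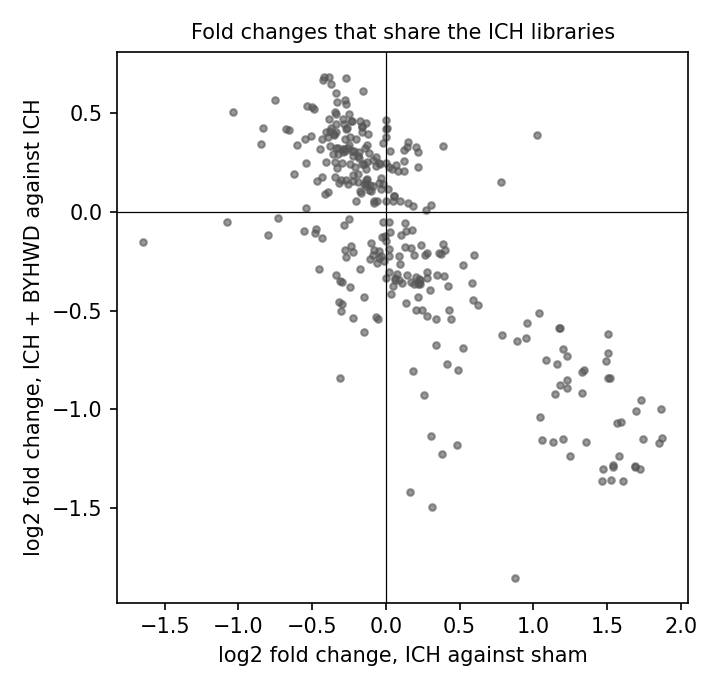
Fitted log2 fold change of ICH against sham on the horizontal axis and of ICH + BYHWD against ICH on the vertical axis, with 1 point for each of the 311 fragments above 0 in all 9 libraries. The points slope downward with a Pearson r of -0.77, where unchanged groups sharing the ICH libraries gave a median of -0.51 over 327 to 354 fragments if these vary independently; with the correlation between fragments kept, 7.74% of reassigned libraries gave a covariance as low as the observed one.

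The libraries of a group were about as similar to each other as to the other groups. The median correlation of log2 CPM across fragments was 0.915 for the 9 pairs within a group and 0.912 for the 27 pairs between groups. In a principal component analysis of the 311 fragments, the first component held 54.3% of the variance. Sham 1 and 2 had scores of -6.71 and -8.89 on it, and ICH 1 and 2 had 6.84 and 13.26. Sham 3 had 2.26 and ICH 3 had -2.31, between the others, and the 3 ICH + BYHWD libraries lay between -1.96 and -1.21.

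**Figure D3:**
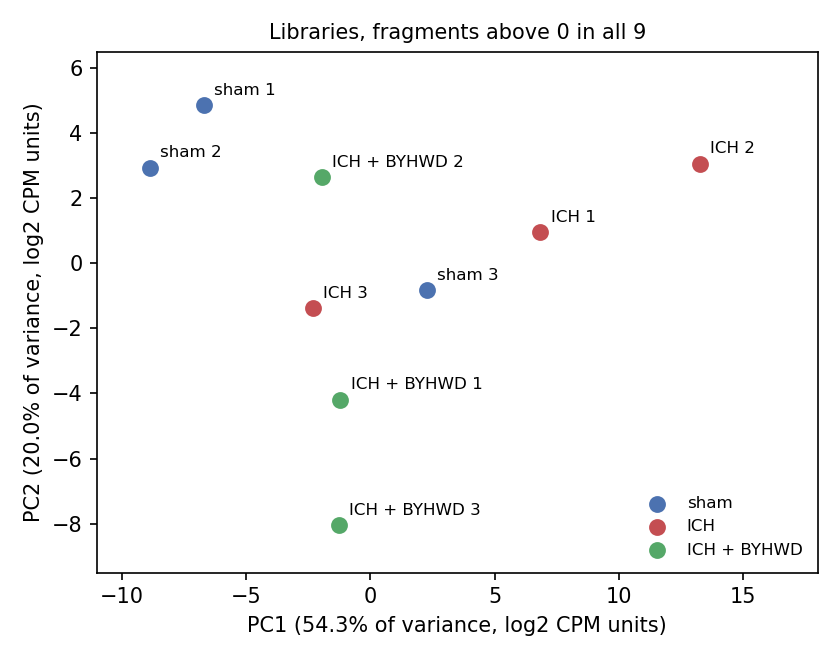
The 9 libraries on the first 2 principal components of log2 CPM over the 311 fragments above 0 in all of them, with 1 point per library coloured by group. Sham 3 and ICH 3 lie near the middle of the first axis, at 2.26 and -2.31, away from the other libraries of their groups.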

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

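All settings that left out zeros, replaced them or used recovered library totals, and the sums over adjoining rows, were added after seeing the data; 23 planned and 10 added settings were run. In the order ICH against sham, ICH + BYHWD against ICH and ICH + BYHWD against sham, the edgeR counts past the threshold were 0 higher and 0 lower, and stayed at 0 under RLE, upper-quartile or no scaling, no low-count filter, limma-voom, limma with trend, the 6 libraries compared, a threshold of 0.1, glmTreat at 1.5-fold, recovered totals, zeros at the lowest listed count, and row sums. The filter of 10 CPM in 3 libraries left the same 455 fragments and so tests nothing. DESeq2, with 87 fragments left without an adjusted p, gave 20 and 8, 4 and 5, and 11 and 6; with zeros at the lowest listed count it gave 6 and 8, 0 and 0, and 0 and 1; on the 311 fragments without a 0 it gave 5 and 4, 0 and 0, and 0 and 3. An unadjusted p under 0.05 with at least 1.5-fold gave 23 and 10, 7 and 9, and 1 and 15, which follows from dropping the adjustment. Leaving out 1 library gave 0 to 40 higher and 0 to 4 lower for ICH against sham, 0 for ICH + BYHWD against ICH, 0 to 17 higher and 0 lower for ICH + BYHWD against sham, and 0 to 27 for any difference among the 3 groups. Each of these highest counts came without sham 3. Of the 44 and 17 fragments called without sham 3, 15 and 15 were at 0 in some library, 29 and 2 were above 0 in all, and 44 and 16 had the same sign with all 9. On the 311 fragments, leaving out sham 3 gave 1 higher and 1 lower for ICH against sham and 0 in the other 2 comparisons.

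The 8 fragments with opposite directions became 0 at an adjusted p under 0.05 in both, 143 at 1.5-fold in both with no test, 46 of that kind on the 311 fragments, 14 with zeros at the lowest listed count, and 3 to 38 with 1 library left out. With zeros at the lowest listed count, 1 of 38 DESeq2 calls with a 0 and 8 of 16 without a 0 were left. For calls with a 0 this cannot tell the listing minimum from a difference between groups, since the replacement shrinks both. For the counts without sham 3 or ICH 3 the cause was not tested. Of 234 alternative values for the 9 named fold changes, 0 reversed, 217 stayed on the same side of the threshold (9 of them from the filter that changed nothing) and 17 passed it, all with DESeq2 or without sham 3. The 9 were picked for a small p in these same libraries, which the alternatives refit, so the kept directions are no separate evidence. Without sham 3, AS-tDR-007227 had an adjusted p of 0.0138 and AS-tDR-000393 one of 0.0363 by edgeR. Without TMM the median log2 fold change moved to -0.23, 0.22 and 0.19 from -0.02, -0.09 and 0.06, and directions are relative to it. No paired analysis was possible because the sample titles share no replicate number. Fragment type, isotype and list alternatives were not run, as the files pair no identifier with these. The listing minimum limits what can be said of any fragment near 134 to 152 TPM.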

Other observations

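The exchange of sham 3 and ICH 3 and the other splits of each pair of groups were tested only after the results were seen, and the sums over adjoining rows were chosen after seeing the row order. Fragments that adjoin at 2 or more places of the row order formed 41 sets, the largest with 28 members. The files do not say what members share. With each remaining fragment counted as a set of 1, there were 233 sets. A set of 8 fragments held 20.5% ± 2.82 of the tags in sham, 17.7% ± 1.41 in ICH and 14.6% ± 3.29 in ICH + BYHWD (SD, n = 3). The 6 fragments with AS-tDR-001297 held 12.9% ± 1.79, 10.4% ± 1.81 and 11.6% ± 2.76. The 9 fragments with AS-tDR-000052 held 5.74% ± 4.64, 13.3% ± 4.66 and 10.3% ± 3.15, with 11.1% in sham 3 and 8.16% in ICH 3. The set of 28 held 3.80% ± 0.70, 5.37% ± 1.30 and 4.43% ± 0.32. Of 181 sets tested with edgeR, sets of 1 included, 0 passed an adjusted p of 0.05 in any comparison, and 18, 14 and 6 had an unadjusted p under 0.05. For a set of 1 the sum is the count of a single fragment, so those sets repeat the test of fragments. DESeq2 and limma were not run on these sums. Fragments above 0 in all 3 libraries of a group and at 0 in all 3 of the other numbered 4 in ICH and 1 in sham, 2 in ICH + BYHWD and 1 in ICH, and 0 between ICH + BYHWD and sham.

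A hypothesis was that fragments listed on the same repeated rows vary together between libraries of a group. The mean correlation of residuals within sets was 0.152 over 228 fragments in 28 sets, and the highest of 1000 shuffles of set membership was 0.0646. Members of a set may therefore share a parent or reads, which the files do not let be tested.

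DESeq2 called 54 fragment and comparison pairs where edgeR called 0. Of these, 38 had a 0 in some library. Once zeros were set to the library's lowest listed count, 1 of these 38 stayed past the threshold. If unlisted fragments lie below that count, the replacement gives the smallest fold they can have. True differences would then lose their calls as well, so the loss cannot show that the listing minimum made these calls. The other 16 were above 0 in all libraries. Of these, 8 of 13 stayed in ICH against sham, 0 of 1 in ICH + BYHWD against ICH and 0 of 2 in ICH + BYHWD against sham. When only the 311 fragments were tested, 8, 0 and 2 of them were called. This argues against zeros made by the listing minimum for the 8 that stayed, and leaves it undecided for the rest of the 16. The edgeR adjusted p of the 16 was 0.316 or higher, and the dispersion common to all fragments was 1.02 against 0.102 in fragments without a 0. On the 311 fragments without a 0, edgeR still called 0 in ICH against sham, with a smallest adjusted p of 0.228. This argues against the higher dispersion as the only reason that edgeR called none. An effect of the haemorrhage on the 8 calls that stayed remains open and was not tested apart from the comparison itself.

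Sham 3 and ICH 3 lay apart from the other libraries of their groups. Sham 3 had correlations of 0.970 and 0.919 with ICH 1 and 2 and of 0.908 and 0.904 with sham 1 and 2. With the 311 fragments without a 0 thinned to 393204 tags in every library, the excess was 0.0382 with an SD of 0.000623 over 100 thinnings, against 0.0387 before. This argues against the number of tags counted as the cause. Thinning removes only counting noise, which is small at counts of 76 or more, so other effects that go with library size were not tested. ICH 3 had correlations of 0.919 and 0.912 with sham 1 and 2 and of 0.917 and 0.855 with ICH 1 and 2. Its mean excess towards sham was 0.0299, but the 0.912 with sham 2 was below the 0.917 with ICH 1. ICH 3 had 0.939 with sham 3, and 0.939, 0.959 and 0.915 with ICH + BYHWD 1, 2 and 3. Its closest library was therefore ICH + BYHWD 2, not a sham library. An exchange of sham 3 and ICH 3 cannot be told apart from variation between rats, haemorrhage size or dissection, none of which the labels give. Of the 10 splits of these 6 libraries, the one that exchanges sham 3 and ICH 3 called the most fragments, 31 against 0 for the labelled groups. That count shows the same structure of the samples as the correlations and is no separate evidence for an exchange.

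Fold changes of ICH + BYHWD against ICH ran against those of ICH against sham. The covariance of -0.250 was below all 100 simulated values for fragments that vary independently, which ranged from -0.106 to -0.049 over 327 to 354 fragments against the observed 311, and this argues against shared ICH libraries alone under that assumption. When whole libraries of residuals, which keep the correlation between fragments, were reassigned to the 3 groups, 130 of 1680 reassignments, or 7.74%, gave a covariance as low as the observed -0.218. The median of the reassignments was -0.064, and the covariance expected from the residual variance of the ICH libraries was -0.090. Shared ICH libraries with fragments varying together can therefore reach the observed value but typically fall short of it. They may account for the pattern in part or in full. An action of the decoction against changes after haemorrhage stays open.

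Among the 10 splits of the 6 libraries in each comparison, a share under 0.05 cannot be reached. Each number of splits as large given here includes the labelled groups themselves. The labelled groups gave 0 calls in each comparison, so that 10 of the 10 splits are as large follows by construction and decides nothing. For ICH against sham the labelled groups gave 0 calls against a highest other of 31, and 41 fragments at an unadjusted p under 0.05 against a highest other of 81, with 2 as large. For ICH + BYHWD against ICH these were 0 against 0, and 30 against 65, with 4 as large. For ICH + BYHWD against sham they were 0 against 5, and 19 against 51, with 3 as large. For any difference among the 3 groups, 19 of 100 splits, the labelled one included, gave as many as the 29 fragments at an unadjusted p under 0.05. The highest other was 68, so chance cannot be excluded for the count of 29, which itself ran from 7 to 72 with 1 library left out.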
